A study of Mus musculus with 6 samples.

How the data were processed

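Total RNA from heart or tibialis anterior of mice was labelled with Cy3 and hybridised to Illumina mouse bead arrays, per the labels' protocols, with material of 3 mice pooled for each of 6 arrays. The array identifiers in the labels share 1 number and differ by a letter, read here as 6 positions of 1 chip. Each of the 6 groups (P14 heart, adult heart and adult tibialis anterior, WT or miR-214 KO) has 1 array. The labels give a mixed strain background. No replicate exists within a group, and p-values over the settings rest on how the KO minus WT difference varies between settings, array noise included. The p-values between settings use the same residual spread.

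Per the file headers, the deposited scanner file holds for each of 45281 probes and each array the mean bead intensity, the standard error of the bead intensity, the count of beads and a detection p-value. These intensities are neither background-subtracted nor normalized between arrays. The authors also deposited processed intensity values of the same arrays. Set against the scanner file, each array of these values keeps the rank order of its scanner signals (rank correlation 1) and lies within 0.343% of the mean of the sorted signals of the 6 arrays. This is the form of quantile normalization on the linear scale without background subtraction, and the software is not given in the sources used here. Their array medians were 54.3 to 54.4. Each column was matched to its sample through the labels, and 0 columns of values were left over.

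Precision rests on the number of arrays, 1 per group. Within an array a probe was read on a median of 43 or 44 beads, with a range of 11 to 164 over all probes. The median bead standard error of detected probes was 4.02% to 4.29% of the signal. Median raw intensities were 52.7 to 57.5, and between 32.9% and 39.7% of probes were detected at a detection p under 0.01, giving 8653 to 9931 detected genes per array.

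Background was corrected with the normexp model of limma 3.58.1 in R 4.3.3, with the mean and SD of the negative controls inferred from the detection p-values and an offset of 16, followed by quantile normalization over the 6 arrays and log2. Further packages were data.table (1.17.8) and matrixStats (1.5.0). The platform annotation gives 1 gene symbol for 34885 probes and several for 18, and 10378 probes are not listed there and stay unnamed. A newer gene table of assembly GRCm38.p6 changed 0 symbols, and was used for names, chromosomes and the order of genes. Each of 19057 named genes is represented by its brightest probe over the 6 arrays.

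For each KO and WT pair the log2 difference is given with no test, over genes detected on at least 1 of the 2 arrays. Where a gene was detected on 1 array only, the fold is a lower bound: the brighter value over the higher of the dimmer value and the lowest detected signal of the dimmer array. Folds between settings and list medians with undetected values raised follow the same rule, array by array, and were added after the data were seen. Counts past 2-fold use normalized values, and counts by lower bounds, also added after the data were seen, stand beside them. The genotype difference over the 3 settings, and the differences between settings, were fitted with limma (lmFit, eBayes with trend) on setting and genotype with 2 residual degrees of freedom, over 10271 genes detected on at least 2 arrays, with Benjamini-Hochberg adjustment. Calls between settings also required 2-fold. Gene lists, 31 in number, were fixed before the data were examined, and 4 were added later. In each pair a list with at least 5 detected members is given by its median and the percentile of that median among 10000 random lists matched on mean expression in 20 bins. Over the settings and between settings lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives.

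Genes were named by a rule fixed before the data were examined. In each pair these are the 8 highest and 8 lowest differences among named genes detected on both arrays, and up to 2 per direction among those detected on 1 array with a bound of at least 2-fold. The miR-214 targets studied in heart, the host locus and the sex-linked genes were always included. Over the settings up to 8 called genes per direction were named, between settings the 8 largest differences per direction past an adjusted p of 0.05, and 2 to 4 members with the largest differences of each list described. Gin1, Ctsc and Ucp3 over the settings, the single probes set beside a named gene and the markers of other tissues were chosen after their values were seen.

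The fit was tested on simulated data with the genes and residual spread of the genotype comparison (10271 genes, 200 of them changed, 5 runs). It called 3.49% of genes changed 1.5-fold, 39.9% of those changed 2-fold and 82.5% of those changed 4-fold, with a mean of 1.4 false calls. In the same simulations a mean of 158.2 unchanged genes reached 2-fold in the P14 pair, where the data had 88 genes past 2-fold in all. The simulated noise includes any variation of the genotype difference between settings. The 158.2 is therefore not the level of chance for a pair. Of simulated lists 4% without a shift fell in the outer tails of the percentile test, and 96% of lists shifted by 0.3 were found.

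Alternatives were quantile normalization within a pair, median centring alone, no background correction, the deposited processed values, detection on both arrays, a detection p of 0.05, averaged probes, 1.5-fold, no filter, no trend, array weights and leaving out settings or arrays. Exclusions of genes of the Dnm3 chromosome, of liver genes (the liver list and the named highest genes of the tibialis anterior pair) and of genes rich in tibialis anterior, and the raising of undetected values, were added after the data were seen. A planned test of genes with predicted miR-214 sites needs transcript sequences and was not analysed here.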

Results

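Gene expression was measured on 6 Illumina bead arrays from mice lacking miR-214, a microRNA transcribed from the Dnm3os RNA inside the Dnm3 gene, and from wild-type (WT) mice. The arrays covered the heart at postnatal day 14 (P14), the heart at 8 weeks of age (adult heart) and the tibialis anterior, a fast muscle of the lower leg, at 8 weeks, with 1 WT and 1 knockout (KO) array in each of these 3 settings. Material from 3 mice was pooled for each array, so a difference within a setting has no replicate check and is given as values. The P14 WT and KO arrays detected 17979 and 17266 of 45281 probes, the adult heart arrays 17907 and 16158, and the tibialis anterior arrays 14892 and 15062. Differences are KO minus WT in normalized log2 intensity. Their median bead standard error, which covers the reading of 1 array only, was 0.10 in each setting.

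The knocked-out microRNA has no value of its own on this array, so the genotype labels could not be checked with it. Dnm3 was not detected on any array, and its host RNA Dnm3os differed by -0.09 in the P14 heart, -0.25 in the adult heart and -0.24 in the tibialis anterior. Nothing ties these probes to the deleted part of the locus, so they check nothing about the deletion. The 4 targets of miR-214 studied in heart are genes of calcium handling and cell death. Slc8a1, the sodium-calcium exchanger, differed by 0.08, -0.06 and -0.32 in the P14 heart, adult heart and tibialis anterior, and Camk2d, a calcium-dependent kinase, by 0.07, -0.54 and 0.11. Bcl2l11, the cell death activator Bim, was higher by 0.45 and 0.75 in the P14 and adult KO hearts and differed by -0.10 in the tibialis anterior. Ppif, the mitochondrial protein cyclophilin D, differed by 0.04, -0.39 and 0.18. The 2 other detected Slc8a1 probes had a mean difference of -0.35 in the P14 heart, against 0.08 for the probe used, and 6 other Camk2d probes a mean of -0.23, against 0.07. Other published miR-214 targets, a list of 14 genes that includes Twist1, Fgfr1 and Ctnnb1, had medians of -0.04, -0.06 and -0.12 in the 3 settings, within the central 95% of 10000 random lists matched on expression. Ctnnb1 (beta-catenin) was lower in both KO hearts, at -0.61 and -0.44. Twist1 and Fgfr1, each not detected on 1 P14 array, were higher in the P14 KO heart by at least 0.59 and 0.58. In that setting 5 of 13 detected members of the list were higher.

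The labels give all animals as male. Xist, the RNA of the inactive X chromosome, was detected on all 6 arrays at log2 values of 9.62 to 10.65. The Y-linked gene Eif2s3y was detected on the P14 WT array alone, at 8.09, and lay between 4.20 and 4.40 on the other 5 arrays. Kdm5d and Uty, also Y-linked, were detected on the same P14 WT array only, at 4.98 and 4.80. The values of these genes go against the sex label, most clearly on the 5 arrays without a detected Y-linked gene, and set the P14 WT array apart from its KO partner.

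The first comparison was of KO and WT hearts at P14. Genes of fast skeletal muscle were higher in the KO heart. The fast troponin subunits Tnnc2 and Tnni2 were higher by 4.24 and 2.08, the calcium buffer Pvalb by 3.84, the fast calcium pump Atp2a1 by 3.33 and the fast myosin light chain Mylpf by 2.80. Tnnt3 and Actn3, detected on the KO array alone, were at least 5.56-fold and 4.58-fold higher, the 2 other detected Actn3 probes having a mean difference of 1.03. Angptl4, an inhibitor of lipoprotein lipase, was higher by 2.10, the mitochondrial carrier Ucp3 by 1.66 and the muscle AMP deaminase Ampd1 by 1.41. Lower in the KO heart were the importin Ipo9 (-2.22), Xirp2, an actin-binding protein of the intercalated disc (-2.11), Bckdhb of branched-chain amino acid breakdown (-1.94), Thap4 (-1.93), Srpr (-1.92), Zfp160 (-1.91), Rgl1 (-1.79) and Zfp367 (-1.68). Cops8, a subunit of the COP9 signalosome, was at least 14.4-fold lower and the Y-linked Eif2s3y at least 9.64-fold lower. Tmem25 was at least 16.7-fold lower by 1 probe, while its 2 other detected probes had a mean difference of 0.20. The second detected probe of Zfp367 differed by -0.47.

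Among 10163 genes detected on at least 1 of the 2 P14 arrays, 24 were at least 2-fold higher and 64 at least 2-fold lower in the KO by normalized values (21 and 54 by lower bounds, with undetected values raised to the lowest detected signal of their array), and 95% of the genes lay between -0.71 and 0.64. Of the fast fibre list, 12 genes were detected, 10 of them higher and 8 by at least 2-fold (7 by lower bounds), with a median of 2.17 at percentile 100 of the random lists (2.14 with undetected values raised to the lowest detected signal). The fetal and stress genes of the heart had a median of -0.20 (percentile 1.84), with 3 of 12 higher. In that list Xirp2 (-2.11), the iron hormone gene Hamp (-0.89) and Nppb (-0.46) were lower, and Tnni1, the slow troponin of the fetal heart, was higher by 0.96. Collagen genes Col3a1 and Col8a1 were lower (-1.15 and -1.10), although the 25 detected genes of extracellular matrix had a median of -0.08 inside the range of random lists. Calcium handling had a median of 0.03 and a mean of 0.25, the latter raised by Pvalb and Atp2a1. With arrays only centred on their medians, the split was 46 higher and 64 lower, and the fetal and stress list moved to a median of -0.05 at percentile 2.91. Without background correction 33 genes passed 2-fold.

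The second comparison was of KO and WT hearts at 8 weeks. Some fast muscle genes were again higher in the KO heart, namely Atp2a1 by 3.88, Tnni2 by 3.09 and Mylpf by 2.47, while Tnnc2 and Tnnt3 were not detected on either adult heart array and the myosin light chain Myl1 was lower (-1.61). Pdk4, the kinase that restrains pyruvate oxidation, was higher by 2.23, as were the mitochondrial leucyl-tRNA synthetase Lars2 (2.23), Clca1 (2.21), Baiap2l1 (2.21) and Nudt6 (2.18). Lypd1 and the apolipoprotein gene Apoa2 were at least 3.75-fold and 2.36-fold higher. Cops8 was at least 37.6-fold lower and Rpe, an enzyme of the pentose phosphate pathway, at least 9.75-fold lower. Thap4 (-2.67), Ipo9 (-2.59), Rgl1 (-2.23), the stem cell receptor gene Lgr6 (-1.83) and Ptcd3 (-1.72) were also lower. The same direction was measured for Slc4a1, the anion exchanger of red blood cells (-2.53), Cyp2a5 (-2.52) and Bpifa1, a secreted protein of the airways (-1.89).

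Of 10080 genes detected in the adult heart pair, 128 were at least 2-fold higher and 52 at least 2-fold lower in the KO by normalized values (120 and 39 by lower bounds), and 95% lay between -0.65 and 0.85. Immediate early genes were higher in the KO, with 10 of 11 detected members above 0 and a median of 0.47 (percentile 99.95). Fos was higher by 1.77 and Atf3 by 1.06. Interferon response genes had a median of 0.37 (percentile 99.68), led by Bst2 (1.81) and Ifi27l2a (1.54), although Rsad2 was lower (-0.69). Genes of oxidative phosphorylation had a median of 0.16 (percentile 99.16), with Cox7b at 0.96 and Ndufb3 at 0.82. The adipocyte list had a median of 0.39 (percentile 98.9), with Ucp1 of brown fat at 0.54 and Adipoq at 0.48. The list of macrophage and antigen presentation genes had a median of 0.21 (percentile 97.75), with H2-Ab1 at 0.76 and Lyz2 at -0.55. The fast fibre list had a median of 0.94 over 7 detected genes (0.63 with undetected values raised to the lowest detected signal), 3 of them at least 2-fold higher. Cell cycle genes were lower, at a median of -0.38 (percentile 0.14) and of -0.21 with undetected values raised in that way. The replication helicase subunit Mcm6 and Nusap1, not detected on the KO array, were at least 2.78-fold and 1.86-fold lower. Genes of glycolysis and glycogen had a median of -0.29 (percentile 0.76), 1 of 15 being higher, with the glucose transporter Slc2a4 at -0.51. Of 4 detected red blood cell genes, Slc4a1 (-2.53) and Alas2 (-1.65) were lower while Hbb-b2 was higher by 1.94.

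In this pair the split became 84 higher and 68 lower with median centring, and 83 genes passed 2-fold without background correction. Several of these lists lost their place among the outer 5% of random lists under another setting. Glycolysis and glycogen genes were at percentile 9.21 with median centring and 6.3 without background correction. Macrophage genes were at 96.7 and 96.1 under these 2 settings, and adipocyte genes at 97.3 without background correction. When the detected probes of a gene were averaged, macrophage, interferon and cell cycle genes were at percentiles 88.9, 72.7 and 5.74.

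The third comparison was of KO and WT tibialis anterior. Genes of plasma proteins made by the liver were higher in the KO muscle. Apoa2 was higher by 3.08, the urinary protein gene Mup3 by 3.02, transthyretin (Ttr) by 2.98, Apoc1 by 2.91, the fibrinogen chain Fga by 2.84, Ahsg by 2.73, and Serpina1d and Ambp by 2.69. The liver enzymes Cyp2c70 and Pon1 were at least 5.77-fold and 5.38-fold higher. Cops8 was at least 37.8-fold and Rpe at least 9.24-fold lower in the KO muscle. Thap4 (-1.94), Ipo9 (-1.84), the sialidase Neu2 (-1.61), the macrophage and adipose gene Retnla (-1.59), Hyi (-1.39), 2610035D17Rik (-1.38), Ptcd3 (-1.34) and Gadd45gip1 (-1.31) followed.

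Of 9112 genes detected in the tibialis anterior pair, 226 were at least 2-fold higher and 43 at least 2-fold lower in the KO by normalized values (145 and 28 by lower bounds), and 95% lay between -0.60 and 0.99. Adipocyte genes were higher in the KO, with 4 of 5 detected members above 2-fold and a median of 1.98, among them Adipoq (2.57), Scd1 (2.08), the hormone leptin, Lep (1.98), and Cidec, at least 3.47-fold higher. Slow fibre genes had a median of 0.59, 6 of 8 being higher, with Tnnc1 at 1.83, Tnnt1 at 1.17 and the slow calcium pump Atp2a2 at 0.93. The fast fibre list had a median of -0.06 inside the random range. Myogenic regeneration genes had a median of 0.70 (0.57 with undetected values raised to the lowest detected signal), including the fetal acetylcholine receptor subunit Chrng (at least 1.37-fold), Ncam1 (0.92) and the neonatal myosin Myh8 (0.77). Genes of the fetal and stressed heart had a median of 0.62, with 9 of 10 higher, led by the stretch-responsive Ankrd1 (2.31) and Hamp (at least 2.86-fold). Atrophy and autophagy genes (median 0.38, mean 0.17, 5 of 9 higher), fibroblast genes (median 0.34, 9 of 9 higher, Mfap5 1.07), heat shock genes (median 0.33, Hspb1 1.16) and interferon response genes (median 0.25, Ifi27l2a 1.71) also lay in the upper 2.5% of random lists. Endothelial genes (median -0.29, 1 of 11 higher, Pecam1 -0.44), smooth muscle and pericyte genes (median -0.22), circadian clock genes (median -0.15, although Per3 was at least 2.21-fold higher) and oxidative phosphorylation genes (median -0.11) lay in the lower 2.5%. The circadian list, with a mean of 0.01, had percentile 2.61 with median centring, and with averaged probes the heat shock, interferon and smooth muscle lists had percentiles 81.8, 94.1 and 3.97. Without background correction 132 genes passed 2-fold, and 120 genes passed among those detected on both arrays.

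**Figure D1:**
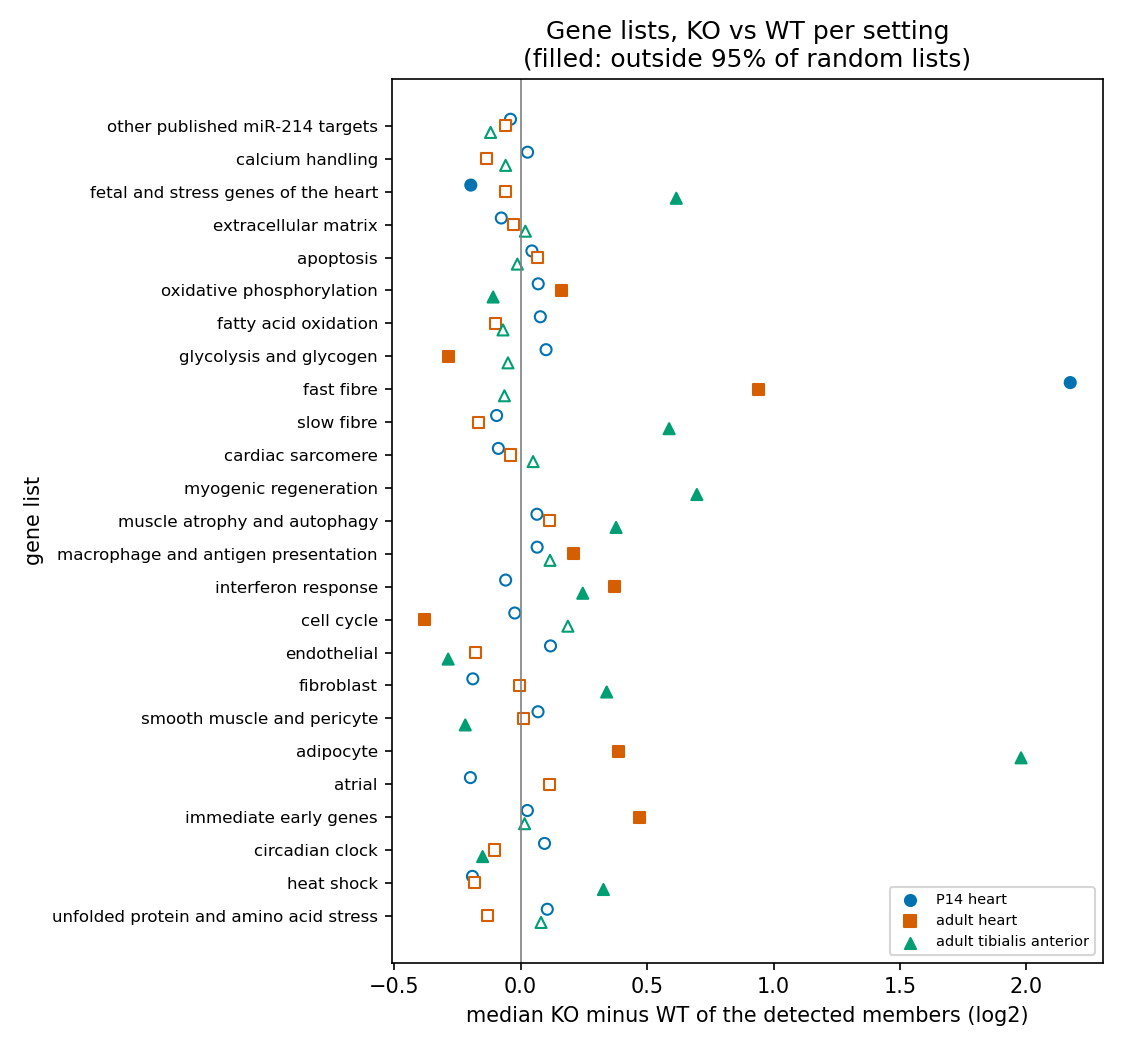
Median KO minus WT log2 difference of the detected members of each gene list fixed before the data were examined, in the P14 heart, adult heart and tibialis anterior, with 1 array per genotype. The fast fibre list stands at 2.17 in the P14 heart and 0.94 in the adult heart, and the adipocyte list at 1.98 in the tibialis anterior.

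Markers of tissues other than the one sampled were read alongside these lists, with 3 of the marker lists (liver, airway and lung, brown fat) chosen after the leading genes had been seen. Of 26 liver list genes on the array, 17 were detected on at least 1 array of the tibialis anterior pair. Of these 17 were higher in the KO and 15 at least 2-fold (13 by lower bounds), with a median of 1.87 (1.63 with undetected values raised to the lowest detected signal). Some members, such as Cps1, Plg and Uox, were detected on the KO array alone. The leading members were Apoa1 (2.54), Kng1 (2.47) and Fgg (2.39). Alb and Fgb, also products of the liver, were not detected on any array. In the hearts the liver list had medians of 0.27 at P14 and -0.17 in the adult. The airway and lung list had a median of 0.52 over 4 detected genes at P14, -0.52 over 7 in the adult heart (percentile 0.07) and 0.83 over 3 in the tibialis anterior. With undetected values raised to the lowest detected signal these medians were 0.37, -0.52 and 0.004, so the rise in the tibialis anterior rests on undetected values. Scgb1a1, secreted by club cells of the airway, reached 12.8 on the adult WT heart array and 11.6 on its KO partner. Brown fat genes had medians of 0.07, 0.42 and 0.02 in the P14 heart, adult heart and tibialis anterior, and Ucp1 read 9.87 and 10.41 on the adult WT and KO heart arrays. In the KO hearts Tnnc2 read 9.52 at P14 and 4.42 in the adult, against 14.74 in the WT tibialis anterior, while Atp2a1 read 10.22 and 9.39 against 14.99. Leaving out genes at least 8-fold higher in the WT tibialis anterior than in the WT heart of that age left 78 genes past 2-fold at P14 and 170 in the adult heart. Leaving out the liver list and the named highest genes of the tibialis anterior pair left 244 there. Liver genes outside that set may remain, so this count does not give the share of liver genes. These exclusions were chosen after the data were seen.

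**Figure D2:**
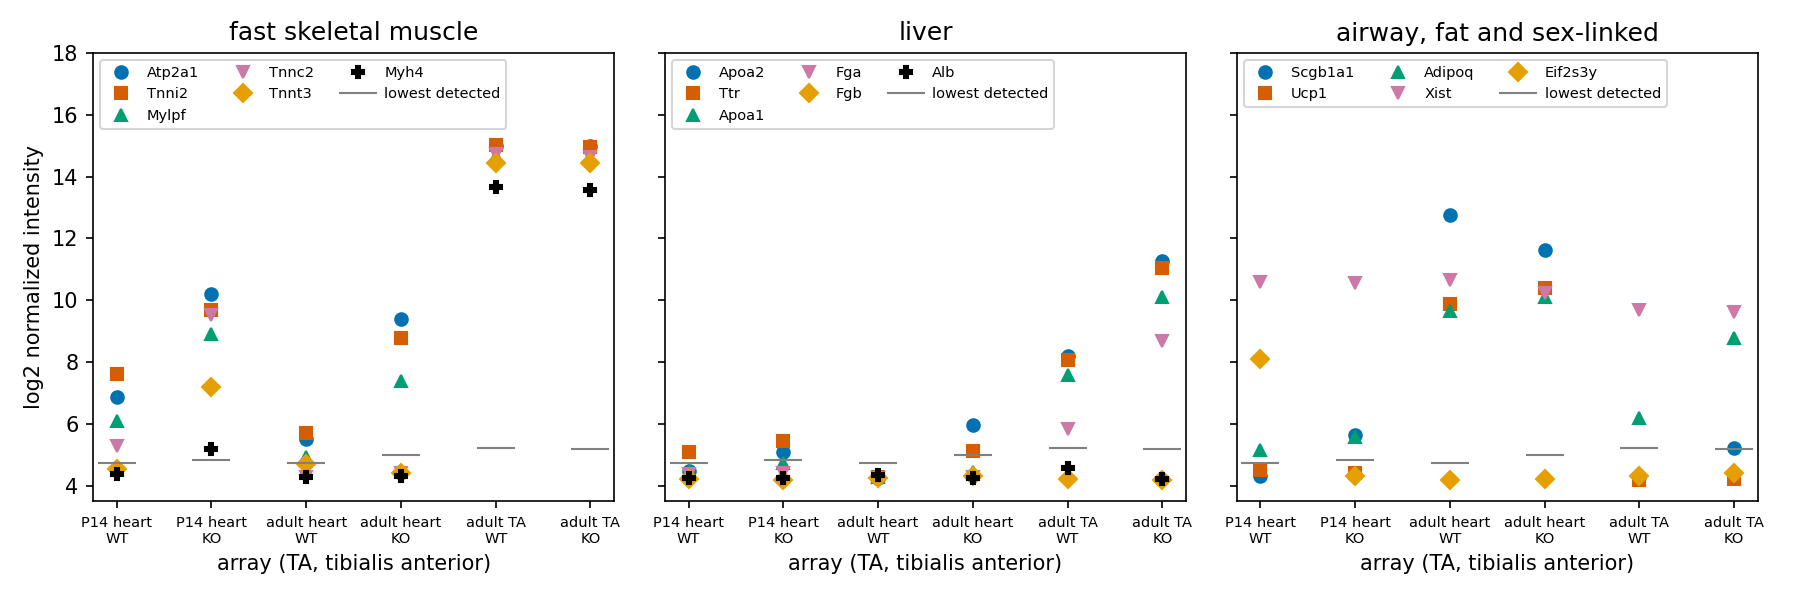
Normalized log2 intensity of marker genes of fast skeletal muscle, liver, airway, fat and sex on each of the 6 arrays (1 point per gene and array), with a grey line at the lowest detected signal of each array. Atp2a1, Tnni2 and Mylpf lie above that line on all 4 heart arrays, Tnnc2 on both P14 heart arrays and Tnnt3 on the P14 KO heart array, and the liver markers Alb and Fgb lie below it on all 6 arrays.

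Across the 3 settings, a genotype difference common to all was tested for 10271 genes. It was called for 7. Cops8 fell most, from 8.67, 10.22 and 10.43 on the WT arrays of the P14 heart, adult heart and tibialis anterior to 4.41, 4.57 and 5.16 on the KO arrays, where it was not detected (adjusted p = 0.000326). Ipo9 fell by 2.22 (SE 0.17, adjusted p = 0.00507) and Thap4 fell by 2.18 (SE 0.17, adjusted p = 0.00524). Rgl1 fell by 1.72 (SE 0.20), and Rpe fell too, each with an adjusted p of 0.0466. Rpe was not detected on the KO arrays, where it was at least 2.65-fold, 9.75-fold and 9.24-fold lower in the P14 heart, adult heart and tibialis anterior. Angptl4 rose by 1.64 (SE 0.17, adjusted p = 0.0294) and the metallothionein gene Mt1 by 1.37 (SE 0.16, adjusted p = 0.0466). Each of the 7 had the same direction in 3 of 3 settings. In the GRCm38.p6 gene table the 5 genes that fell lie on the chromosome of Dnm3, with Rgl1 73, Ipo9 138, Thap4 319, Cops8 371 and Rpe 556 protein-coding genes away from it. Of 10271 tested genes, 550 lie on that chromosome. Not called, with the next smallest p-values, were Gin1, on the same chromosome and not detected on the KO arrays (adjusted p = 0.0682), the protease gene Ctsc (-1.25, adjusted p = 0.0801) and Ucp3 (1.31, adjusted p = 0.0809).

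These adjusted p-values are from limma, with 2 residual degrees of freedom and the variation of the KO minus WT difference between settings counted as noise. In simulated data of this design 39.9% of genes changed 2-fold were called. With only 1 probe detected for each gene that fell, no second probe bears on them. Cops8, Ipo9 and Thap4 were called under 10 of 10 alternatives, Angptl4 under 6, and Mt1, Rgl1 and Rpe under 3 each. The count was 18 with median centring, 4 without background correction, 3 without the adult heart pair, 13 without the tibialis anterior pair and 20 without the P14 pair.

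**Figure D3:**
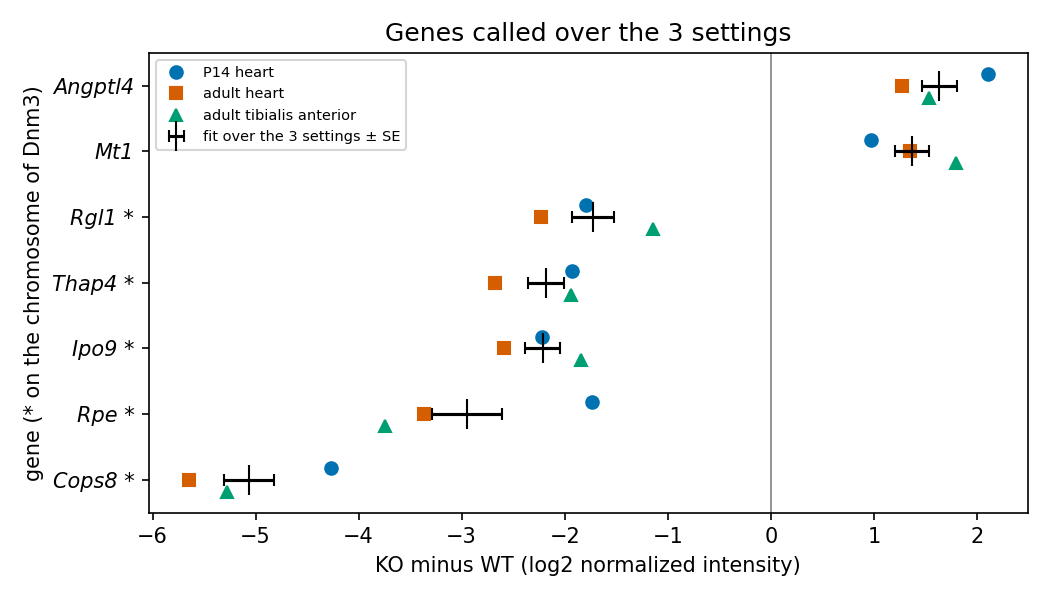
KO minus WT log2 difference of the 7 genes called over the settings, in the P14 heart, adult heart and tibialis anterior (1 array per genotype and setting, each from 3 pooled mice), with the fitted difference ± SE and an asterisk for genes on the chromosome of Dnm3. Angptl4 and Mt1 lie above 0 in all 3 settings and Rgl1, Thap4, Ipo9, Rpe and Cops8 below 0, Rpe and Cops8 being drawn from KO values that were not detected.

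Of 25 lists tested over the settings with camera, 3 rose, as an average over the settings that need not hold in each. In the P14 heart the interferon response list had a median of -0.06, with 4 of 10 higher. The adipocyte list had a median of 0.07 there, with 2 of 4 higher. In the tibialis anterior the fast fibre list had a median of -0.06, with 2 of 12 higher. The fast fibre list had an adjusted p of 0.0334, and the interferon response and adipocyte lists an adjusted p of 0.0466 each. All 3 calls were lost with an estimated correlation, at an adjusted p of 0.903. Fast fibre genes had a median of 0.85 over the settings, 9 of 12 being positive, with Atp2a1 at 2.40 and Mylpf at 1.73, neither called by itself. Adjusted over the list alone, 3 fast fibre genes were called, against 0 over all genes tested. Of 10 interferon genes 8 were positive, and of 7 adipocyte genes 6, with no gene of either called over all genes or adjusted over the list alone. In the fatty acid oxidation list 1 gene, Angptl4, was called over all genes and 4 were called adjusted over the list alone. That list had a median of -0.06 but a mean of 0.18, and its camera adjusted p was 0.459. Calcium handling had a median of -0.06 and a mean of 0.14 (adjusted p = 0.872), with 0 genes called over all genes and 0 adjusted over the list alone. Other published miR-214 targets had a median of -0.08, 4 of 13 being positive (adjusted p = 0.459), again with 0 called either way.

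The KO minus WT differences of the settings were compared across the 7830 genes detected on all 6 arrays. The differences of the P14 and adult hearts had a Pearson r of 0.466 and a Spearman rho of 0.473. The adult heart and tibialis anterior gave 0.170 and 0.0699, and the P14 heart and tibialis anterior -0.0316 and -0.0622. The 3 pairs share no array, and genes are not independent replicates. Among genes detected in both pairs, 6 were at least 2-fold higher in both KO hearts by normalized values where independent lists would share 0.234, and 9 were lower in both where they would share 0.277. The adult heart and tibialis anterior shared 21 higher genes against 1.45, and 11 lower genes against 0.154. The P14 heart and tibialis anterior shared 1 higher gene against 0.242 and 7 lower genes against 0.188. By lower bounds the shared counts were 6 higher and 7 lower for the hearts, 18 and 11 for the adult heart and tibialis anterior, and 1 and 6 for the P14 heart and tibialis anterior. Of 8492 genes detected in all settings, Angptl4 was at least 2-fold higher in all 3, and Cops8, Ctsc, Gin1, Ipo9, Rgl1, Rpe and Thap4 were at least 2-fold lower by their normalized values, although the bound for Gin1 at P14, where the KO value was not detected, is 1.59-fold. All of these 7 except Ctsc lie on the chromosome of Dnm3.

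Age was compared within the heart, with the WT and KO arrays as the 2 samples of each age. Elastin and the collagen genes Col26a1 and Col3a1 were higher in the P14 heart than in the adult heart, and Scgb1a1, Ucp1 and Adipoq were lower. Elastin (Eln) was higher by 3.97 (SE 0.22, adjusted p = 7.31e-05), reading 11.21 ± 0.21 at P14 and 7.24 ± 0.24 in the adult (SD, n = 2). Col26a1, not detected on 1 adult array, was at least 11.7-fold higher, Nrep was higher by 3.48, the potassium channel subunit Kcne1 by 3.47, the histone gene H2ac15 by 3.26, Col3a1 by 3.16 and Spon2 by 3.15, with adjusted p-values from 6.52e-05 to 0.000846. Pvalb, not detected on 1 adult array, was at least 7.78-fold higher (adjusted p = 0.0257), with an SD of 2.71 between the 2 P14 arrays. Scgb1a1, Ucp1 and Wfdc2, not detected on at least 1 P14 array, were at least 128.6-fold, 41.1-fold and 19.1-fold lower at P14 (adjusted p = 0.000166 for Scgb1a1). Cyp2e1 (-5.42), Inmt (-4.98), Ces1d (-4.74), Car3 (-4.67) and Adipoq (-4.50) were also lower, the last with an adjusted p of 0.000806.

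At an adjusted p under 0.05 and 2-fold, 289 genes were higher and 373 lower at P14. Camera called 12 of 25 lists, 5 up and 7 down. Of the extracellular matrix list 17 of 25 genes were higher and 1 lower (20 changed when adjusted over the list alone), with Col1a1 at 2.76, and the list rose (adjusted p = 2.13e-14). Of the cell cycle list 12 of 17 were higher (16 adjusted over the list alone), with Prc1 at 3.07 and Cdk1 and Top2a at least 4.55-fold and 3.91-fold higher (adjusted p = 4.67e-12 for the list). With an estimated correlation these lists had an adjusted p of 0.305 and 0.347. Fast fibre, endothelial and fatty acid oxidation lists also rose, and with an estimated correlation the adjusted p of all 5 lists that rose lay between 0.305 and 0.567. In the fast fibre list 2 genes, Pvalb and Casq1, were called (4 adjusted over the list alone), in the endothelial list 1 (3) and in the fatty acid oxidation list 3 (3). The adipocyte list fell (6 of 7 called, 7 adjusted over the list alone) and so did the atrial list, with 5 of 6 called, 6 adjusted over the list alone, and Sln at -3.17, Myl7 at -1.99 and Myl4 at -1.94. With an estimated correlation both had an adjusted p of 0.322. Circadian clock genes fell (6 of 13 called lower, 1 higher, Ciart -2.61, Dbp -2.44), as did macrophage and antigen presentation genes (5 of 13, H2-Ab1 -2.81, Cd74 -2.64), both at an adjusted p of 0.347 with an estimated correlation. Adjusted over the list alone, 11 circadian and 5 macrophage genes changed. The interferon, glycolysis and unfolded protein lists fell with 2, 2 and 1 genes called, against 8, 5 and 5 adjusted over the list alone. With an estimated correlation the adjusted p of all 7 lists that fell lay between 0.322 and 0.567. Of the other-tissue marker lists added after the data were seen, airway and lung fell at P14 (median -1.95, 5 of 6 called lower, 5 adjusted over the list alone, adjusted p = 1.35e-05) and so did brown fat (median -0.27, mean -1.15, 2 of 6, 2 adjusted over the list alone, adjusted p = 0.0435). Their adjusted p was 0.141 and 0.266 with an estimated correlation, and the liver list was not called (adjusted p = 0.0760). Median centring moved the median of all tested genes from 0.01 to 0.22 and the split to 513 higher and 258 lower, so the directions are relative to quantile normalization. Without the adult heart KO array 399 genes were called, and without background correction 398.

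The tibialis anterior differed from the adult heart in the contractile genes of each tissue. The atrial peptide gene Nppa was at least 861-fold lower in the tibialis anterior (adjusted p = 1.96e-08), where it was detected on 1 of 2 arrays. The cardiac myosin Myh6, detected on both, was lower (-9.02, SE 0.16, adjusted p = 4.20e-08). Cardiac myosin-binding protein Mybpc3 was at least 286-fold lower, Fhl2 261-fold, Myl7 219-fold, the cardiac ryanodine receptor Ryr2 169-fold, Nppb 126-fold and Mybphl 121-fold, with adjusted p-values up to 3.89e-07. The fast muscle genes were not detected on at least 1 adult heart array, so their folds are bounds too. Actn3 was at least 1043-fold higher, Tnnc2 906-fold (adjusted p = 5.31e-05), Tnnt3 764-fold, Pvalb 675-fold, Ampd1 561-fold, Myh4 429-fold, Mylk2 346-fold and the skeletal ryanodine receptor Ryr1 307-fold. These genes separate heart from skeletal muscle in the direction that the tissue labels give.

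In all, 869 genes were higher and 1092 lower in the tibialis anterior. Camera called 13 of 25 lists, 3 up and 10 down. The fast fibre list rose, with 12 of 12 genes called (12 adjusted over the list alone), as did glycolysis and glycogen with 8 of 15 higher and 2 lower (14 adjusted over the list alone, Gys1 2.48, Hk1 at least 7.62-fold lower). Myogenic regeneration genes rose with 5 of 7 higher and 1 lower (7 changed adjusted over the list alone, Myf6 at least 56.7-fold and Chrna1 at least 14.3-fold higher). With an estimated correlation these 3 lists had an adjusted p of 0.347, 0.477 and 0.469. Fatty acid oxidation fell, with 13 of 23 genes lower and 1, Ucp3, higher (20 changed adjusted over the list alone, Acot1 -2.69). Cardiac sarcomere, slow fibre and atrial genes fell, with 9 of 16, 8 of 10 and 6 of 6 called lower and 1 cardiac sarcomere gene called higher. Adjusted over the list alone, 11, 8 and 6 of them changed. Fatty acid oxidation, cardiac sarcomere and atrial genes had an adjusted p of 0.347 with an estimated correlation, and slow fibre genes an adjusted p of 0.469. Macrophage (8 of 13 lower), endothelial (5 of 11), fibroblast (7 of 10), interferon (5 of 10), adipocyte (6 of 7) and apoptosis (3 of 16, Bcl2l11 -2.05) lists also fell, with 9, 9, 10, 6, 6 and 8 genes adjusted over the list alone. With an estimated correlation the adjusted p of these 6 lists lay between 0.347 and 0.477. Of the added marker lists, airway and lung (4 of 6 called lower, 6 adjusted over the list alone) and brown fat (4 of 6, 4 adjusted over the list alone) fell, each with an adjusted p of 0.0148 and, with an estimated correlation, an adjusted p of 0.236. The liver list rose, with 5 of 10 higher and 1 lower (7 adjusted over the list alone, adjusted p = 0.0466), and had an adjusted p of 0.548 with an estimated correlation. Median centring moved the median of all tested genes from -0.05 to -0.25 and the split to 651 higher and 1542 lower.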

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

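The tests of a strain segment, of the called genes by chromosome, of direct repression, of normalization and of skeletal muscle RNA were chosen only after the result they measure was seen, and those of a probe variant, of liver RNA and of other splits were set before, although the liver list itself was written after liver genes were seen to lead the tibialis anterior.

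The 5 genes called lower in the KO over the settings lie on the chromosome of Dnm3, which prompted a count: with calls in either direction, 5 of 550 genes tested there and 2 of 9721 elsewhere, Angptl4 and Mt1, were called (Fisher's exact two-sided p = 8.30e-06, a description of the pattern and not a separate test of it). Direct loss of repression by miR-214 would raise its targets, so the direction of these 5 genes, by which they were picked (0 higher), argues against it as their cause without a separate test. A chromosome segment of another strain, carried along with the knockout on the mixed background, may lower several genes. Among genes not called, the share at an unadjusted p under 0.05 was 11.7% on that chromosome and 9.51% elsewhere (odds ratio 1.27, 95% interval 0.952 to 1.66, Fisher's exact two-sided p = 0.0863), so the condition set for a segment was not met. Of the genes under 0.05, 38 of 64 there and 380 of 924 elsewhere were lower in the KO (Fisher's exact two-sided p = 0.00567). That direction was not part of the condition and does not tell a segment from variants under the probes, so a segment stays open. A sequence variant under the probe also stays open, since the 5 genes have 0 other detected probes. Lgr6 and Gin1, also on that chromosome, had a second detected probe that was lower too, which bears on them and not on the 5. For Lgr6 it was -1.53 beside -1.83 in the adult heart. For Gin1 it was detected on 2 arrays and was -0.29, -0.97 and -1.23 in the P14 heart, adult heart and tibialis anterior, beside -1.08, -2.10 and -1.95. An effect of the genotype itself on these genes stays open and was not tested.

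Some genes typical of another tissue were higher in KO arrays, liver genes in the tibialis anterior and fast skeletal muscle genes in the hearts. The airway and lung list went the other way in the adult heart, with a median of -0.52. Liver genes were also detected on the WT tibialis anterior array, with Apoa2 at 8.20 and Ttr at 8.07. Normalization is argued against for the liver genes, whose median of 1.87 was still 1.74 at its lowest under median centring or normalization within the pair. Liver RNA in the KO tibialis anterior pool may be the source. The size set in advance was met (a median of 1.87), with 17 of 17 detected liver genes higher. Detection on 1 array sufficed, so members such as Cps1, Plg and Uox entered through their KO value alone, which favours a higher reading. A further condition, added after the values were seen, was that Alb and Fgb rise, and neither was detected on any array. No array here shows that their probes can report, while Fga read 8.68 and Fgg 8.00 on the KO tibialis anterior array. Their absence therefore cannot weigh against liver RNA, and the explanation is held open. Skeletal muscle RNA in the P14 KO heart pool stays open, with 2 of 5 genes abundant in tibialis anterior and undetected in the WT heart at least 2-fold higher (40%, Clopper-Pearson 95% interval 5.27% to 85.3%) and all 5 higher, whereas for the adult heart 0 of 8 such genes were at least 2-fold higher (upper limit 36.9%), which argues against it there as the whole source. Picking genes undetected on the WT array favours a higher reading in the KO. Genes of 1 array pair are not independent replicates, so these intervals may be too narrow. An effect of the genotype in these tissues stays open, untested with 1 pool per group.

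The count of 7 genes called over the settings was set against the other splits of the 6 arrays into 3 and 3. Of 10 splits, 3 gave at least 7 genes, the real one included, and the highest of the others gave 27. With 10 splits no share under 0.05 can be reached. Among the 4 splits that take 1 array from each setting, the real one gave 7 and the other 3 gave 0 each. The splits with 27 genes place each heart age wholly on 1 side and so set only the WT against the KO tibialis anterior, a structure of the samples.

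Some genes had normalized values at least 2-fold apart in opposite directions in 2 settings, and with 1 array per genotype and setting these differences between settings were not tested. Atf3, a stress-induced transcription factor, was lower in the P14 KO heart (-1.37) and higher in the adult KO heart (1.06) and KO tibialis anterior (2.24), so that P14 minus adult heart was -2.44 and P14 minus tibialis anterior -3.61. For 5 genes 1 side of a pair was not detected, so that the normalized differences are not exact and bounds are given with undetected values raised to the lowest detected signal of the array. For Klk1b22, a kallikrein gene, P14 minus adult heart was -2.61 (bound -1.56) and P14 minus tibialis anterior -3.18 (bound -1.65), and the bounds within the pairs, -0.90, 0.66 and 0.75, are under 2-fold. The airway gene Scgb1a1 was lower in the adult KO heart (-1.15) and higher in the P14 KO heart by at least 0.89, a difference of 2.47 (bound 2.04). Against the tibialis anterior, the P14 heart differed by -2.13 for Col8a1 (-1.10 and 1.03), by -2.74 for Rab6b (bound -1.93, from -1.03 and 0.90) and by -3.09 for Zfp52 (bound -2.78, from -1.31 and 1.46). The adult heart minus the tibialis anterior was -4.77 for the cytochrome P450 gene Cyp2a5 (bound -4.28, from -2.52 and 1.76), -3.65 for Cyp2f2 (-1.71 and 1.94) and 2.98 for Retnla (1.39 and -1.59).

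Among probes with no gene symbol, which no comparison used, 1 probe was at least 2-fold lower in the KO in all 3 settings, by a mean of -1.79 (-2.95 in the P14 heart, -1.11 in the adult heart and -1.31 in the tibialis anterior).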

How the results depend on the processing

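The exclusions of Dnm3-chromosome genes, liver genes and tibialis anterior genes and the raising of undetected values were chosen only after the data were seen, and the other alternatives were set before. Of the genes run under the alternatives, none that was called by a test or past 2-fold changed sign, and no list outside the central 95% did. In single pairs the genes run were the highest and lowest of each pair and those always included. Genes named only as list members, or only after their values were seen, were not run. Of 937 values under alternatives 5 did change sign, each from a difference under 2-fold: Slc8a1 and Camk2d at P14 and Bcl2l11 in the tibialis anterior with averaged probes, and Xist at P14 with averaged probes and with median centring. The balance of called genes over the settings, 2 higher and 5 lower, turned to 11 and 7 with median centring, 14 and 6 without the P14 heart and 7 and 6 without the tibialis anterior. At P14 against the adult heart it turned to 513 higher and 258 lower with median centring.

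Without background correction, and with the deposited processed values, which are in effect the same setting, 33 genes passed 2-fold in the P14 heart, 83 in the adult heart and 132 in the tibialis anterior. That setting gave 4 genes over the settings, 398 between the ages, and a correlation of 0.487 between the P14 and adult heart differences. Background left in the signal compresses differences of dim genes by construction, so signal over background limits these folds. At 1.5-fold the counts were 824, 1126 and 715, a wider threshold by construction. Detection on both arrays left 120 genes in the tibialis anterior and raising undetected values to the lowest detected signal left 173 there, 75 in the P14 heart and 159 in the adult heart, where by construction fewer genes pass. A detection p of 0.05 gave 88, 180 and 269 genes, the counts of the main threshold.

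The genotype count of 7 became 18 with median centring, and 3 with no filter, with averaged probes or without the trend, each of these 3 being among the 7. Leave-one-out fits gave 3 to 20 genes, with 3 without the adult heart, 13 without the tibialis anterior and 20 without the P14 heart. Without genes on the chromosome of Dnm3 limma called 0, with 938 at an unadjusted p under 0.05 in that setting. Between the ages the count was 399 to 626 with 1 array left out, the lowest without the adult heart KO array, the lone array of an age being assumed to vary like the others. Between the tissues the counts were 1351 to 2212 over the alternatives, against 1961. Except where stated, the cause was not tested.

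With an estimated correlation camera called 0 lists over the settings, 0 between the ages and 0 between the tissues, and fry called 0, 7 and 15. Over genes detected on at least 2 arrays the correlation of differences was 0.406 for the P14 and adult hearts and -0.00228 for the P14 heart and tibialis anterior. Of 110 list medians under alternatives 94 stayed in the same outer 2.5% and 16 did not. Of 405 values of named genes in single pairs 221 moved by no more than the bead standard error and 184 by more. Of 352 values between settings 349 kept their call, and of 70 over the settings 45 did.

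The planned results on predicted miR-214 sites were not run, since transcript sequences were not used here.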

Other observations

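The tests of time of day and of RNA of another tissue were chosen only after their result was seen, and the test of a fasting-like state was set before the genes of its list were looked at. Genes in the next paragraph were chosen after their values were seen, and their differences within a setting have no test.

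In the KO tibialis anterior sarcolipin (Sln), an inhibitor of the calcium pump, was higher by 2.02, the muscle LIM protein gene Csrp3 by 1.23, the protease inhibitor Timp1 by 1.91, the growth factor-induced Egr1 by 1.08 and the survival gene Bcl2 by 1.06, while Chac1 of the amino acid stress response was lower (-1.08) and the myosin light chain Myl3 was lower (-0.63). Timp1 was also higher in the adult KO heart (0.75). In the P14 KO heart the clock gene Bhlhe40 was lower (-1.03), as was Nr1d2 (-0.89), the ATP synthase subunit Atp5a1 (-0.92) and the junctional protein gene Jph1 (-0.77), and the protease gene Ctsl was higher by 1.07. The cell cycle inhibitor Cdkn1a was higher in each KO, by 0.86, 1.16 and 0.64, with an adjusted p of 0.141 over the settings, and the stress gene Ddit4 by 0.96, 0.55 and 1.03 (adjusted p = 0.169).

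Angptl4 and Mt1, called higher over the settings, and Ucp3, Cdkn1a and Ddit4, which were not called, are among genes that respond to fasting or glucocorticoids. Angptl4 was called under 6 of 10 alternatives and Mt1 under 3, and neither when genes on the chromosome of Dnm3 were left out. A hypothesis is that the KO animals were in a fasting-like or glucocorticoid-like state. A list of 30 further such genes, 28 of them tested and looked at for the first time in this test, may be shifted up (camera p = 0.000611, adjusted p = 0.00122 over the 4 added lists, median 0.15, 22 of 28 positive, with medians of 0.12, 0.18 and 0.12 in the P14 heart, adult heart and tibialis anterior), but with an estimated correlation the adjusted p was 0.244 and no gene was called over all genes or adjusted over the list alone. A different time of day of tissue collection stays open, since the clock genes, tested by rotation for change in either direction with fry, had a mixed p of 0.0423, which met the condition set, but 0.264 when adjusted over 25 lists, with Per3 at 0.84 and Bhlhe40 at -0.57. RNA of another tissue in the KO pools stays open too: the 29 higher genes among the 40 with the smallest p had a median of 0.615 in the P14 heart, where the liver list had a median of 0.27 and the airway list 0.52. The condition set against it needed both list medians near 0, and only the airway median, over 4 detected genes, missed it. With undetected values raised to the lowest detected signal that median was 0.37 and would have met it. The outcome therefore turns on undetected values and decides nothing. An effect of the genotype itself on these genes stays open and was not tested.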
